A study of Mus musculus with 14 samples.

How the data were processed

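Gene expression was measured on single-colour Agilent mouse whole-genome arrays in 14 samples of mouse mast cells. Per the labels, BMMCs were cultured with IL-3 for 4 to 6 weeks, cocultured cells were kept for 96 h with Swiss 3T3 fibroblasts and 100 ng/ml stem cell factor, and 450 ng of RNA was labelled for each array. The strain label was the same for both genotypes. Per the file headers and the labels, the authors obtained the deposited spot intensity values with Agilent Feature Extraction 9.5.1.1, with spatial and multiplicative detrending on and the further background correction off. Scaling between arrays is not in the deposited scanner files. The authors also deposited an annotated table of 25193 probes, chosen by a rule not given in the sources used here. Its raw intensity columns equal the scanner values to within 1 unit. Its normalized intensity columns equal the raw ones minus 1 constant per array of 67 to 172, again to within 1 unit, which left 59.0% to 59.8% of values below 0. In the deposited table of 24 selected probes, 8 of 14 column headings held the values of another array, knockout BMMCs and wild-type cocultured cells being exchanged, so only its probe list was used. Its 14 call columns, as they stand in the annotated table, were not used.

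The scanner's processed signal was put on the log2 scale, and the 75th percentile of each array was subtracted. Control spots and spots marked as outliers by the scanner software were left out, 74 to 326 per array, and spots of 1 probe were averaged. Of 41174 probes, 24844 were named by accession in a table of RefSeq genes, 7855 by symbol or synonym, and 8475 kept the name in the file. Probes well above background on at least 3 arrays were kept, 23625 in all, and 32 were dropped for missing values. The probe with the highest mean stood for each gene, which gave 16009 genes, 13037 of them with a symbol in the reference. Positions are those of the probes on mm9 in the scanner files. The 75th percentile of signal was 69.4 to 176 units, and 0 to 3 spots per array were saturated.

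Differences were tested with limma 3.58.1 in R 4.3.3 and data.table (version 1.17.8), in 1 fit of the 4 groups with 5 contrasts. These were coculture in wild-type cells, coculture in knockout cells, knockout against wild-type before and after coculture, and the interaction. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes, with calls at an adjusted p under 0.05. "Passed", "rose" and "fell" refer to that threshold. Where a gene was well above background on no array of a group, its fold was computed against the lowest signal called well above background and is given as a lower bound. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 26 lists and 5 contrasts together, and again with the correlation estimated for each list. Of 17 calls with the preset correlation, 0 held with the estimated one. Wild-type and knockout BMMC arrays of the same number deviated together from their group means, with r of 0.197, 0.496 and 0.490 across genes for numbers 1 to 3, although wild-type BMMC 1 deviated more like knockout BMMC 4 (r = 0.359). Each of these 3 pairs also shared a slide and matched in Y-linked signal, so number, slide and donor sex cannot be separated there. Pairing was applied as an alternative. Across coculture equal numbers need not mean the same donor, since Y-linked signal was absent on wild-type BMMC 1 and present on wild-type cocultured 1. The size of the response was compared by exact permutation of genotype labels within BMMCs and within cocultured cells.

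The lists covered mast cell granule proteases, heparin and chondroitin sulfate synthesis, histamine and serotonin, phospholipase A2 enzymes, prostanoids, leukotrienes, IgE receptor and Kit signalling, transcription factors and surface receptors. Others covered cytokines, cell cycle, cholesterol, glycolysis and hypoxia, interferon response, endoplasmic reticulum stress, lysosome and exocytosis, and immediate early genes. Marker lists covered fibroblasts, macrophages, neutrophils, dendritic cells with MHC class II, basophils, eosinophils, lymphocytes, erythroid cells and megakaryocytes. The lists, the tests, the alternatives described as planned and the rule for naming genes were fixed before the data were examined. That rule named Pla2g3 in every comparison. It named Hdc, Cma1, Mcpt4, Tpsb2, Cpa3, Ndst2, Ptgdr, Hpgds, Ptgds, Ptgs1, Ptgs2, Kit, Fcer1a and Ms4a2 in coculture of wild-type cells and in both knockout comparisons. It further named the 10 largest rises and falls that passed without overlap and were above background on every array of a group, up to 4 passing members of each list with the lowest adjusted p, or up to 2 where none passed, and the genes of the authors' selected table. Results that name items withheld for evaluation were left out. Xist, Eif2s3y and the genes named from chromosomes 4 and 11 in the closing section were chosen after their values were seen.

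Alternatives to the scaling were quantile normalization, the median of each array, normexp background correction with an offset of 50 followed by quantile normalization, and the authors' normalized values with a floor of 1. Others were no filter on dim probes or a filter on all arrays, slide as a fixed or random block, a replicate block, array weights, a fold threshold of 2, every probe on its own, the arrays of only the groups compared, and leaving out each array. A term for Y-linked signal, omission of slide 4, omission of its cocultured pair and the authors' raw values were chosen after seeing the data. With median scaling the median log2 change of all genes was -0.24 in wild-type coculture, 0.31 for knockout after coculture and 0.34 for the interaction, against -0.06, 0.05 and 0.14 with the 75th percentile.

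The test was tried on simulated data in which 200 genes were changed. At log2 changes of 1, 2 and 4 it recovered 13.4%, 67.2% and 92.4% in wild-type coculture and 7.46%, 55.2% and 87.9% in knockout coculture. It recovered 17.9%, 53.7% and 90.9% for knockout before coculture, 13.4%, 53.7% and 92.4% after it, and 1.49%, 26.9% and 69.7% for the interaction, with 3 to 8 false calls. The simulated noise was independent between genes, with 1 SD per gene for all 4 groups. Deviations shared by many genes and a spread that differs between groups are not in it, so these shares need not hold for the arrays.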

Results

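The arrays measured RNA in mouse bone marrow-derived mast cells (BMMCs), which are immature mast cells grown from bone marrow with IL-3, and in such cells after 96 h of coculture with Swiss 3T3 cells, a mouse fibroblast line, and stem cell factor. The cells came from mice labelled wild-type or knockout for Pla2g3, which encodes the group III secreted phospholipase A2, an enzyme that cleaves membrane phospholipids. Wild-type BMMCs filled 3 arrays, knockout BMMCs 4, wild-type cocultured cells 4 and knockout cocultured cells 3. Per the labels, over 97% of the BMMCs and over 99% of the cocultured harvest carried the mast cell markers Kit and FcεRIα. Between 17691 and 23023 probes per array, 43.0% to 55.9% of those on the array, were well above background, and the number of arrays limits the precision of each value. Levels below are log2 signals relative to the 75th percentile of the same array, so that 0 is that percentile. The labels do not say whether replicates came from separate mice or cultures, so the p-values measure the spread between these samples.

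The groups were spread over 4 slides. Slide 1 held no wild-type cocultured array, slide 3 no knockout cocultured array, and slide 4, scanned on another date, no wild-type BMMC array. Each slide otherwise held 1 array of each group, except that slide 3 held 2 wild-type cocultured arrays. Levels of all genes correlated between replicates at r of 0.957 to 0.968 in wild-type BMMCs, 0.938 to 0.977 in knockout BMMCs, 0.899 to 0.977 in wild-type cocultured cells and 0.917 to 0.981 in knockout cocultured cells, across genes that are not independent replicates. Wild-type cocultured 3 and knockout cocultured 3, both on slide 4, each stood with the cocultured arrays of the other genotype on the second principal component.

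**Figure D1:**
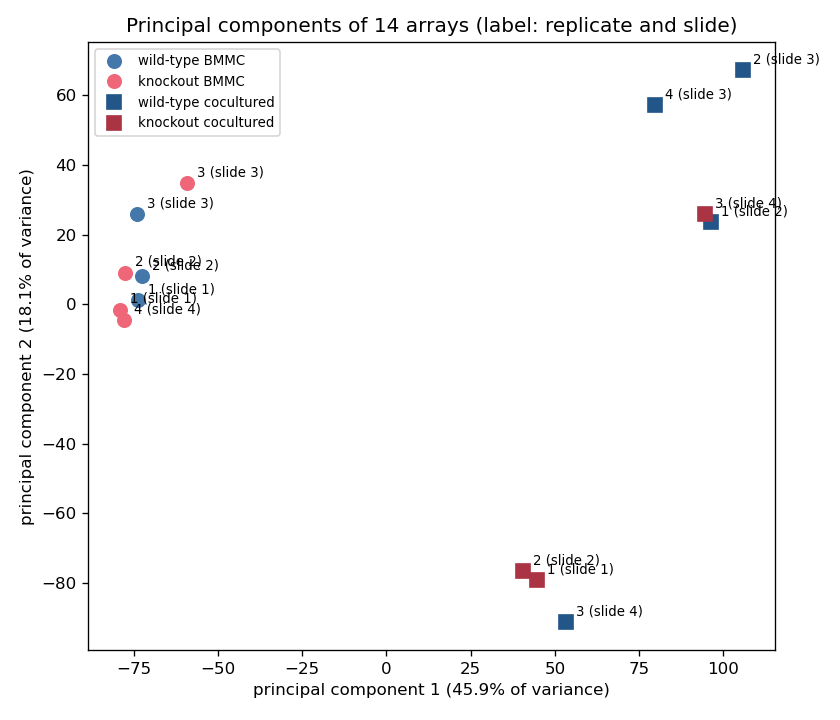
Each point is 1 array placed by its scores on the first and second principal components of all genes (axes in component units, 45.9% and 18.1% of the variance), with symbols for the 4 groups and replicate labels. BMMC arrays lie between -79.2 and -59.3 on the first component and cocultured arrays between 40.5 and 105.9, and wild-type cocultured 3 lies at -91.4 on the second component, near knockout cocultured 1 at -79.3 and knockout cocultured 2 at -76.7.

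Wild-type cells after coculture were compared with wild-type BMMCs to see what coculture with fibroblasts and stem cell factor did to RNA of the harvest. The labels give stem cell factor for cocultured arrays only, so its effect and that of the fibroblasts cannot be separated. The Pla2g3 probe (A_51_P402868, chromosome 11, 3393221 to 3393280 on mm9) was at -3.80 ± 0.87 (SD, n = 3) before and -3.48 ± 0.96 (SD, n = 4) after coculture, a log2 change of 0.31 (SE 0.54, adjusted p = 0.784), and was well above background on 1 of 3 and 2 of 4 arrays. Hdc, the enzyme that makes histamine, rose from 2.78 ± 0.79 (SD, n = 3) to 6.02 ± 0.45 (SD, n = 4), a log2 change of 3.24 (SE 0.50, adjusted p = 0.00117). Hpgds, the hematopoietic prostaglandin D synthase, rose from 0.57 ± 0.20 (SD, n = 3) to 2.56 ± 0.39 (SD, n = 4), a log2 change of 2.0 (SE 0.26, adjusted p = 0.000342). Ptgs2, the inducible cyclooxygenase, was below background on all BMMC arrays and at least 29.9-fold higher after coculture (adjusted p = 0.000454), a call that ended with the authors' normalized values (adjusted p = 0.0552). Gata1, a transcription factor of the mast cell, erythroid and megakaryocyte lineages, fell by 1.99 (SE 0.24, adjusted p = 0.000191). On slides 2 and 3, which held both groups, the difference was 3.82 and 3.21 for Hdc, 2.09 and 1.82 for Hpgds, at least 4.89 and 3.59 for Ptgs2 and -2.14 and -1.92 for Gata1.

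In this comparison limma called 2064 of 16009 genes (12.9%), 964 higher and 1100 lower, and 1875 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 4218 genes, where chance would give 800. In 4076 genes (25.5%) no array of one group overlapped the other, against 5.71% by chance. The count was 3785 without the cocultured pair of slide 4, an omission chosen after the arrays had been compared, and 1200, 1167 and 1119 without wild-type BMMC 1, 2 and 3.

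Granule proteases of mast cells were the first group. Of 19 measured members of the protease and serglycin list, 7 rose, 0 fell and 12 did not pass. When adjusted over the list alone, 9 passed. The tryptase Tpsab1 was at least 347-fold higher (adjusted p = 6.31e-05), Mcpt8 rose by 2.95 (SE 0.48, adjusted p = 0.00178) and Mcpt2 by 4.57 (SE 1.02, adjusted p = 0.0109). Gzmb, which encodes granzyme B, rose by 1.48, Mcpt9 was at least 1.57-fold higher, Cma2 rose by 4.86 and Mcpt1 was at least 46.1-fold higher (adjusted p = 0.0489). The connective tissue chymase Mcpt4 was at 1.78 ± 1.21 (SD, n = 3) before and 5.93 ± 2.98 (SD, n = 4) after (log2 change 4.15, adjusted p = 0.0584), and the tryptase Tpsb2 at 5.96 and 6.89 (0.93, adjusted p = 0.135). Abundant granule and receptor genes did not pass. They were the chymase Cma1 (-0.25, adjusted p = 0.657), the carboxypeptidase Cpa3 (-0.29, adjusted p = 0.568) and the stem cell factor receptor Kit (-0.27, adjusted p = 0.650). The IgE receptor chains Fcer1a (-0.35, adjusted p = 0.568) and Ms4a2 (-0.32, adjusted p = 0.720) did not pass, nor did the heparin sulfotransferase Ndst2 (-0.56, adjusted p = 0.589). The protease list as a whole had a median log2 change of 0.93 (camera adjusted p = 0.00495), a call lost at adjusted p = 0.747 with an estimated correlation, and its median was 0.71 and 1.32 within slides 2 and 3 and 1.42 without wild-type cocultured 2. Mcpt1, Mcpt2, Mcpt4 and Cma2 were low on wild-type cocultured 3, where Mcpt1 was below background at -6.36. The call of Mcpt1 ended in 12 of 14 omissions of 1 array, at adjusted p up to 0.132 without wild-type BMMC 2, that of Cma2 in 6, and those of Gzmb and Mcpt9 in 1 each. Calls of Mcpt1, Mcpt2, Cma2, Gzmb and Mcpt9 ended with at least 1 other scaling, at adjusted p up to 0.237 for Mcpt9 with normexp background correction.

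Histamine and glycosaminoglycan genes changed one by one rather than as lists. Of 10 measured histamine and serotonin genes, Hdc and the monoamine oxidase gene Maoa (3.39, SE 0.76) rose, 0 fell and 8 did not pass, with 2 passing when adjusted over the list alone (median 0.57, camera adjusted p = 0.374). Of 26 heparin and chondroitin sulfate genes, 1 rose and 2 fell. Csgalnact1, which starts chondroitin chains, was at least 5.92-fold higher, and Chst12 (-1.46, SE 0.30) and Chsy1 (-2.05, SE 0.47), also chondroitin enzymes, fell (6 passing when adjusted over the list alone, median -0.28, of either sign by scaling, camera adjusted p = 0.982). Calls of Maoa and Chsy1 ended without at least 1 wild-type BMMC array, at adjusted p up to 0.0645, and those of Chst12 and Chsy1 with the authors' normalized values, at 0.0886 and 0.053.

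Lipid mediator genes moved in both directions. Of 16 prostanoid genes, 4 rose and 1 fell, with 7 passing when adjusted over the list alone (median 0.36, camera adjusted p = 0.0855, called in 3 alternative settings). Besides Hpgds and Ptgs2, the prostaglandin E synthase Ptges was at least 13.3-fold higher and the prostaglandin F receptor Ptgfr at least 2.29-fold higher, while the constitutive cyclooxygenase Ptgs1 did not pass (-0.71, SE 0.62, adjusted p = 0.529). The prostaglandin D receptor Ptgdr and the other prostaglandin D synthase Ptgds were above background on at most 1 and 2 arrays and were not tested. Of 10 leukotriene genes, 1 rose and 3 fell, with 5 passing when adjusted over the list alone (median -1.17, camera adjusted p = 0.112). The leukotriene B4 receptors Ltb4r1 (-3.96, SE 0.83) and Ltb4r2 (-3.39, SE 0.64) and the leukotriene C4 synthase Ltc4s (-1.88, SE 0.51) fell, and the exporter Abcc1 rose by 0.96. Of 14 phospholipase A2 genes, only Pla2g15, a lysosomal enzyme, passed, and fell by 2.58 (1 passing when adjusted over the list alone, median 0.27, camera adjusted p = 0.777). The call of Abcc1 ended in 9 of 14 omissions of 1 array, at adjusted p up to 0.129, that of Ltc4s in 6, at up to 0.111, and that of Pla2g15 without wild-type BMMC 3, at 0.0807. Another scaling ended the calls of Abcc1, Ltc4s, Ltb4r1 and Ptgfr, at adjusted p up to 0.289 for Abcc1 with median scaling.

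Signalling genes changed at single members, and transcription factors fell more often than they rose. Of 26 IgE receptor and Kit signalling genes, 2 rose and 1 fell, the kinase Fyn (1.89, SE 0.44) among the rises and the phosphoinositide 3-kinase subunit Pik3cd (-2.26, SE 0.28) as the fall, with 3 passing when adjusted over the list alone (median -0.06, of either sign by scaling, camera adjusted p = 0.986). Of 20 mast cell transcription factors, 1 rose and 5 fell, with 8 passing when adjusted over the list alone (median -0.63, camera adjusted p = 0.0693, called in 3 alternative settings). Gata1, Ikzf2 (-1.84, SE 0.36) and Bhlhe40 (-1.31, SE 0.34) were among the falls, and Cebpb rose by 1.62 (SE 0.35). Stat5b fell on its main probe (adjusted p = 0.0486) and was at -1.19 and 0.31 on its 2 other probes. Of 28 mast cell surface receptors, the Mas-related receptor Mrgprb1 was at least 14.7-fold higher and Tlr4 (-1.66) and Il2ra (-1.87) fell, with 7 passing when adjusted over the list alone (median 0.21, camera adjusted p = 0.765). Calls of Fyn, Bhlhe40, Tlr4 and Il2ra ended without at least 1 array, at adjusted p up to 0.144 for Tlr4 without wild-type BMMC 2. These 4 and the calls of Cebpb and Mrgprb1 also ended with at least 1 other scaling, at adjusted p up to 0.185 for Bhlhe40 and 0.134 for Mrgprb1 with the authors' normalized values.

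The cytokine and glycolysis lists were called by camera with the preset correlation in wild-type cells. Of 24 cytokine and chemokine genes, 7 rose, 1 fell and 16 did not pass, with 9 passing when adjusted over the list alone. Tnf rose by 3.63 (SE 0.57), the neutrophil attractant Cxcl1 was at least 243-fold, Cxcl10 at least 59.0-fold and the stem cell factor gene Kitl at least 2.27-fold higher. The median was 1.1 (camera adjusted p = 0.000713), or 0.83 with genes below background in one group at their bound, and 0.35 and 0.32 within slides 2 and 3, or 0.04 and 0.22 with readings below background at the lowest signal well above it. Cxcl10 did not pass with normexp background correction (adjusted p = 0.0508). The list's call was lost at adjusted p = 0.747 with an estimated correlation and at 0.116 with the authors' normalized values. Of 25 glycolysis and hypoxia genes, 13 fell, 1 rose and 11 did not pass, with 20 passing when adjusted over the list alone. The aldolase Aldoc (-2.88, SE 0.42), the phosphofructokinase Pfkl (-3.18, SE 0.56) and the oxygen sensor Egln1 (-2.04, SE 0.36) fell, and Ndrg1, which hypoxia induces, rose by 2.50 (SE 0.40). The median was -1.40 (camera adjusted p = 1.7e-07) and -1.61 and -2.20 within slides 2 and 3, and the call was lost at adjusted p = 0.790 with an estimated correlation.

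Stress, cycle and housekeeping lists were not called in wild-type cells in the main fit. Of 23 immediate early and dissociation stress genes, Klf4 (5.97), Atf3 (5.15), Dusp2 (4.19) and the NF-κB inhibitor Nfkbia (3.56) rose and 0 fell (4 passing when adjusted over the list alone, median -0.25, of either sign by scaling, camera adjusted p = 0.779). Of 22 endoplasmic reticulum stress genes, Chac1 (2.69), Herpud1 (1.31) and the transcription factor Atf4 (1.24) rose and 0 fell (3 passing when adjusted over the list alone, median -0.23, of either sign by scaling, camera adjusted p = 0.779). Of 25 cholesterol synthesis genes only Cyp51 passed and rose by 1.70 (median 0.17, of either sign by scaling, camera adjusted p = 0.765). Of 23 interferon response genes, Isg15 (2.59) and Gbp2 (1.49) rose and Usp18 (-2.54) fell (median 0.01, of either sign by scaling, camera adjusted p = 0.846). Without wild-type BMMC 2 that list was called, at 0.77 (camera adjusted p = 0.0121). Of 29 lysosome and exocytosis genes, the syntaxin Stx11 rose by 3.55 (SE 0.39) and the vesicle protein Rab3a fell by 2.46 (median -0.14, of either sign by scaling, camera adjusted p = 0.825). Of 30 cell cycle genes 0 passed, with Cdt1 at 1.02 and Mcm6 at -0.73 (median -0.14, of either sign by scaling, camera adjusted p = 0.846). Of these, the calls of Atf3, Dusp2, Chac1, Atf4, Cyp51, Isg15, Gbp2 and Rab3a ended without at least 1 array, at adjusted p up to 0.161 for Gbp2 without wild-type BMMC 3. With at least 1 other scaling the calls of Atf3, Dusp2, Herpud1, Atf4, Cyp51, Isg15 and Gbp2 ended, at adjusted p up to 0.101 for Herpud1 with median scaling.

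Markers of other cell types were read on the same arrays. Of 33 measured fibroblast markers, 26 rose, 1 fell and 6 did not pass, with 29 passing when adjusted over the list alone. The collagens Col3a1 and Col1a1 were at least 361-fold and 241-fold higher, the collagen chaperone Serpinh1 at least 305-fold, the matrix proteoglycan Dcn at least 146-fold and Igfbp7 at least 50.3-fold. These were below background on every BMMC array, while the protease inhibitor Timp3 was at least 72.3-fold lower. The median was 4.74 (camera adjusted p = 8.53e-18), or 3.59 with genes below background in one group at their bound, and 4.76 and 6.40 within slides 2 and 3 (3.57 and 4.59 with readings below background at the lowest signal well above it), and the call was lost at adjusted p = 0.747 with an estimated correlation. Kitl, Cxcl1, Cxcl12, Ptgs2, Ptges and Il1r1, genes that fibroblasts also express, stood higher beside these markers. Ptgs2 did not follow the markers between cocultured arrays. Knockout minus wild-type, it was at 0.14 and -2.72 within slides 2 and 4, where the fibroblast list was at -2.29 and 1.98. Cdh11 did not pass on its main probe (-0.24) but was at 5.18 and 5.12 on other probes. Of 13 macrophage markers, Cd14 (4.04) and Cd68 (2.69) rose and the Fc receptor Fcgr1 (-3.97) fell (4 passing when adjusted over the list alone, median -0.70, camera adjusted p = 0.982). The basophil list had Mcpt8 as its only rise among 3 measured genes (median -0.03, of either sign by scaling, camera adjusted p = 0.530). Of 6 dendritic cell and MHC class II markers only H2-Ab1 passed (-2.05, SE 0.45), and of 5 erythroid markers only the transcription factor Klf1 did, without being well above background on any array of either group, so that no fold is given. None of the 4 neutrophil, 2 eosinophil, 3 lymphocyte and 8 megakaryocyte markers passed, with S100a9 at least 3.98-fold lower and Gp1ba at -0.94 (SE 0.30, adjusted p = 0.0541) the lowest p in their lists. The calls of Cd68, H2-Ab1 and Klf1 ended without at least 1 array, at adjusted p up to 0.163 for Cd68 without wild-type BMMC 1 (1.74), and those of Cd14, Cd68 and Klf1 with at least 1 other scaling, at up to 0.455 for Klf1 with normexp background correction. In wild-type cells the test pointed up beside a median below 0 for the heparin, IgE receptor, cell cycle, endoplasmic reticulum stress, lysosome, immediate early, macrophage and basophil lists, and down beside a median above 0 for the megakaryocyte list.

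Outside the lists, the largest rises without overlap included the pentraxin Ptx3, at least 156-fold, the growth factor Ptn, at least 116-fold, the oncostatin M receptor Osmr, at least 110-fold, and the chemokine Cxcl5, at least 188-fold. All 4 were lower on wild-type cocultured 3 than on the other wild-type cocultured arrays, as Col1a1 and Col3a1 were. The largest falls included the immunoglobulin heavy chain probes Igh (-8.95, SE 1.05), Ighv1-54 (-8.28, SE 0.91) and Ighv1-12 (-7.39, SE 0.69), the adhesion molecule Jaml (-8.13, SE 1.59), Pigz (-6.69, SE 0.51) and the peptide gene Grp (-6.89, SE 2.03). Trgv4, Cyp4a12b and Mgarp were at least 64.8-fold, 109-fold and 41.4-fold lower. The call of Grp ended in 8 of 14 omissions of 1 array, at adjusted p up to 0.147, and at 0.126 with the authors' normalized values, as did that of Ptn, at 0.0736. Of the 22 genes in the table of significant genes deposited by the authors, 13 rose and 1 fell, with 18 passing when adjusted over the list alone, a list drawn from these arrays and so no independent evidence. Its members Il1r1 (at least 64.2-fold), Cxcl12 (at least 28.0-fold), Cx3cl1 (5.66) and Ccl1 (4.78) rose, while the call of Ccl1 ended without 1 of 5 arrays, at adjusted p up to 0.100, those of Cxcl12, Cx3cl1 and Ccl1 ended with the authors' normalized values, at 0.058, 0.0813 and 0.0588, and Tnfsf14 (2.50), Il1b (1.42), Ptgir (1.39), Ccl9 (0.57), Ccl2 (0.20) and Il4 (-0.84) did not pass.

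**Figure D2:**
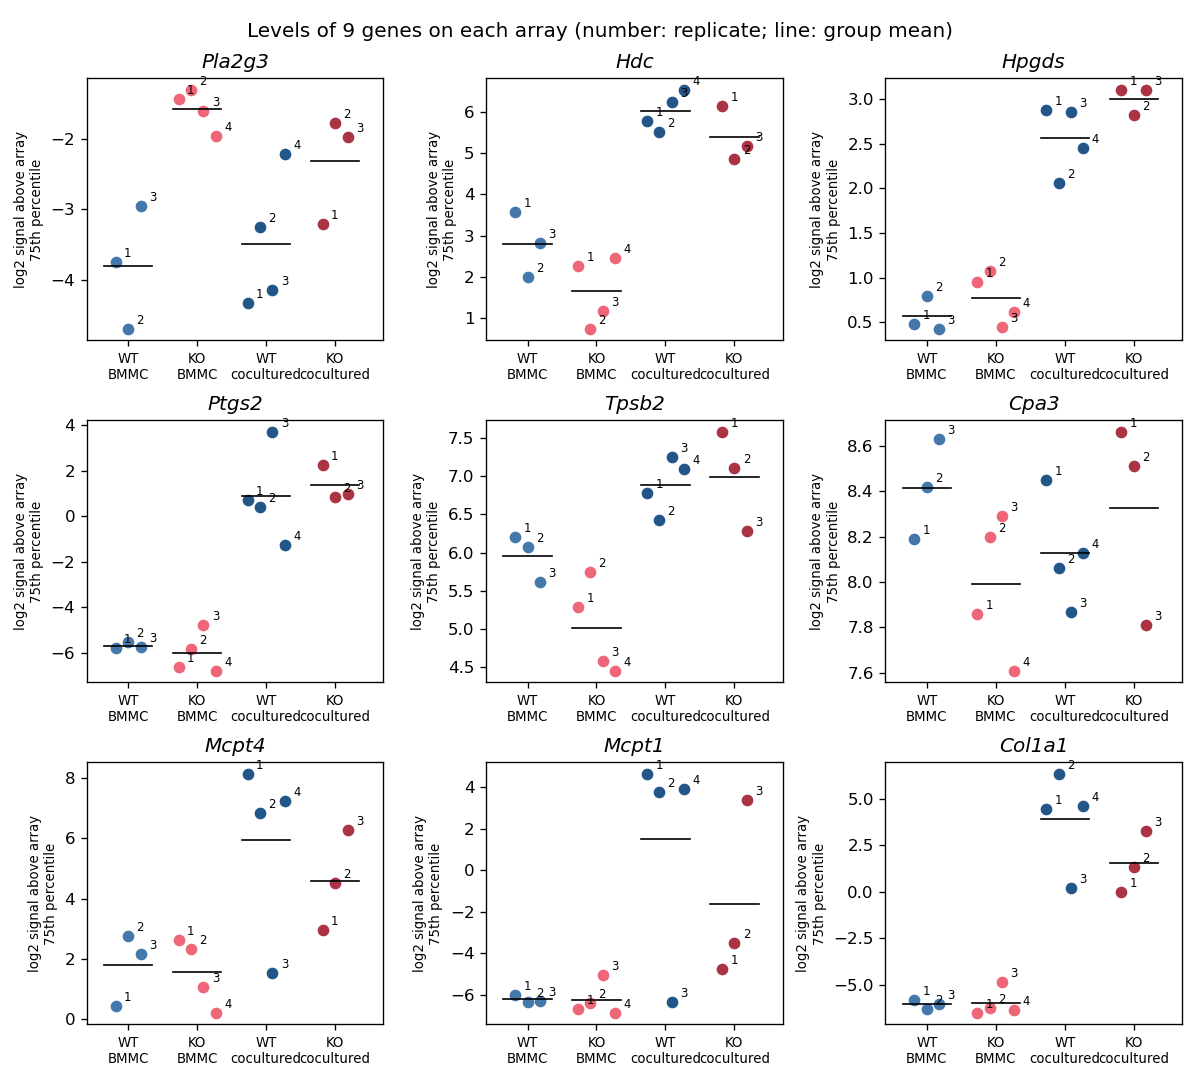
Each panel plots the log2 signal of 1 gene above the 75th percentile of its array, by group, with a point per array numbered by replicate and a line at the group mean. Hdc and Hpgds stand higher in every cocultured than in every BMMC array, while Mcpt1 stands below background at -6.36 on wild-type cocultured 3.

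Knockout cells after coculture were compared with knockout BMMCs to follow the same step in cells labelled as lacking Pla2g3. The Pla2g3 probe was at -1.57 ± 0.28 (SD, n = 4) before and -2.32 ± 0.78 (SD, n = 3) after coculture, a log2 change of -0.74 (SE 0.54, adjusted p = 0.392), well above background on every array of both groups. Hdc rose from 1.65 ± 0.83 (SD, n = 4) to 5.39 ± 0.67 (SD, n = 3), a log2 change of 3.74 (SE 0.50, adjusted p = 0.000571), and Hpgds from 0.77 ± 0.29 (SD, n = 4) to 3.01 ± 0.17 (SD, n = 3), a change of 2.23 (SE 0.26, adjusted p = 0.000219). Ptgs2 was at least 40.4-fold higher (adjusted p = 0.000272), and Tpsb2 rose by 1.96 (SE 0.38, adjusted p = 0.00535). Gata1 fell by 2.04 (SE 0.24, adjusted p = 0.000228). Within slides 1, 2 and 4 the difference was 3.89, 4.11 and 2.73 for Hdc, 2.15, 1.74 and 2.49 for Hpgds, 2.28, 1.35 and 1.83 for Tpsb2 and -2.17, -1.79 and -2.47 for Gata1.

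In knockout cells limma called 2285 of 16009 genes (14.3%), 1245 higher and 1040 lower, 1934 of them by at least 2-fold, with 4684 at an unadjusted p under 0.05. Groups did not overlap in 4497 genes (28.1%), against 5.71% by chance. The count was 4946 without the cocultured pair of slide 4, 1329 without knockout BMMC 1, 1329 without knockout BMMC 2, 1523 without knockout BMMC 3 and 1069 without knockout cocultured 1. Of the genes called in wild-type and in knockout cells, 1376 were shared and all of them moved the same way, 645 up and 731 down. Independent lists would share 75 and 71, a baseline that is too low, since both comparisons use the same spread per gene from 1 fit.

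Mast cell lists in knockout cells held many of the genes named above. Of 19 granule protease genes, 7 rose and 0 fell, with 9 passing when adjusted over the list alone. Tpsab1 (7.65, SE 1.09), Mcpt8 (3.64, SE 0.48), Tpsb2, Mcpt9 (1.5, SE 0.33) and Mcpt2 (4.00, SE 1.02) were among them. Cma2 (3.51, adjusted p = 0.0867), Mcpt4 (3.03, SE 1.33, adjusted p = 0.150) and Mcpt1 (at least 5.14-fold higher, adjusted p = 0.217) did not pass. The median was 1.48 (camera adjusted p = 0.000479) and 1.27, 1.0 and 0.86 within slides 1, 2 and 4, a call lost at adjusted p = 0.747 with an estimated correlation. Of 10 histamine and serotonin genes Hdc rose (1 passing when adjusted over the list alone, median 0.47, camera adjusted p = 0.482). Of 26 heparin and chondroitin sulfate genes, the heparan sulfotransferase Hs6st1 (0.94) and Ugdh (0.92) rose and Chst12 (-1.0) fell (0 passing when adjusted over the list alone, median -0.15, camera adjusted p = 0.788). Of 26 IgE receptor and Kit signalling genes, 3 rose and 1 fell, Fyn (2.08) and the adaptor Lat (1.48) among the rises and Pik3cd (-2.35) as the fall (4 passing when adjusted over the list alone, median 0.16, of either sign by scaling, camera adjusted p = 0.564). Of 20 transcription factors, Cebpb rose by 2.35 and 4 fell, Gata1, Lyl1 (-2.49) and Stat5b (-1.12) among them (6 passing when adjusted over the list alone, median -0.47, camera adjusted p = 0.0572, called in 14 alternative settings). Of 28 surface receptors, Mrgprb1 (at least 6.29-fold), Cd44 (1.49) and Adora2a (0.87) rose and Il2ra was at least 4.27-fold lower (5 passing when adjusted over the list alone, median 0.30, of either sign by scaling, camera adjusted p = 0.846). Calls of Mcpt2, Mcpt9, Hs6st1, Ugdh, Chst12, Lat, Lyl1, Stat5b, Mrgprb1, Cd44 and Adora2a ended without at least 1 array, at adjusted p up to 0.223 for Lat without knockout cocultured 1. Leaving out knockout cocultured 3 brought Chst12 to -0.61 and lowered the fitted change of Mrgprb1 most. Of these, all but Lyl1 and Stat5b also ended with at least 1 other scaling, as did the calls of Mcpt8 and Fyn, at adjusted p up to 0.483 for Mcpt2 with the authors' normalized values.

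Lipid mediator genes in knockout cells included 4 rises and 2 falls among 16 prostanoid genes (7 passing when adjusted over the list alone, median 0.65, camera adjusted p = 0.0612, called in 4 alternative settings), with Ptges at least 7.44-fold higher, the prostacyclin receptor Ptgir up by 2.06 (SE 0.45) and the prostaglandin E receptor Ptger4 down (-2.33, SE 0.44). Ptges, a gene that fibroblasts also express, stood higher beside fibroblast markers on the same arrays (list median 2.88). Of 10 leukotriene genes, Abcc1 rose by 1.65 (SE 0.28), and Ltb4r1 (-3.45), Ltb4r2 (at least 6.27-fold lower) and the cysteinyl leukotriene receptor Cysltr2 (-1.91) fell (5 passing when adjusted over the list alone, median -0.80, camera adjusted p = 0.193). Of 14 phospholipase A2 genes, Plaat3 (2.47) and Pnpla8 (0.99) rose and Pla2g15 (-2.05) fell (4 passing when adjusted over the list alone, median -0.17, of either sign by scaling, camera adjusted p = 0.982). Calls of Ptgir, Cysltr2, Plaat3, Pnpla8 and Pla2g15 ended without at least 1 array, at adjusted p up to 0.211 for Plaat3 without knockout cocultured 1, and Pla2g15 stood at -1.25 without knockout cocultured 3. Scaling in another way ended the calls of Ptges, Ltb4r1, Cysltr2, Plaat3, Pnpla8 and Pla2g15, at adjusted p up to 0.277 for Pnpla8 with the authors' normalized values.

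Of 24 cytokine and chemokine genes in knockout cells, 7 rose and 1 fell, with 14 passing when adjusted over the list alone. Tnf rose by 4.68 (SE 0.57), and Cxcl1, Cxcl10 and Kitl were at least 63.2-fold, 39.4-fold and 1.42-fold higher, beside fibroblast markers that stood higher on the same arrays (list median 2.88), Kitl and Cxcl1 being genes that fibroblasts also express. Calls of Cxcl10 and Kitl ended with normexp background correction (adjusted p = 0.0891 and 0.0737), and that of Cxcl10 with the authors' normalized values (0.118). The median of the cytokine list was 1.85 (camera adjusted p = 0.00161), 1.46 with bounds, and 2.58, 3.15 and 0.90 within slides 1, 2 and 4, or 2.16, 1.76 and 0.40 with readings below background at the lowest signal well above it, a call lost at adjusted p = 0.790 with an estimated correlation. Of 25 glycolysis and hypoxia genes, 10 fell and 1 rose, with 12 passing when adjusted over the list alone. Aldoc (-3.03), Pfkl (-3.08) and the kinase Pdk1 (-5.02) fell and Ndrg1 rose by 2.50. The median was -0.64 (camera adjusted p = 0.000176) and -0.19, -0.73 and -1.09 within slides 1, 2 and 4, or -0.38 without knockout BMMC 3, a call lost at adjusted p = 0.966 with an estimated correlation. Of 22 endoplasmic reticulum stress genes, 5 rose and 0 fell, with 5 passing when adjusted over the list alone. Chac1 (3.62), the asparagine synthetase Asns (2.48), Herpud1 (1.82) and Atf4 (1.65) were among them. That list's median was 0.28 (camera adjusted p = 0.0405), turned to -0.11 with the authors' normalized values, and was 0.96, 0.70 and -0.40 within slides 1, 2 and 4. Its call was lost at adjusted p = 0.966 with an estimated correlation, at 0.182, 0.156 and 0.172 with quantile normalization, normexp background correction and the authors' normalized values, and at 0.178 with slide as a fixed block. Without knockout BMMC 1, knockout cocultured 1 and knockout cocultured 2 the adjusted p was 0.0728, 0.169 and 0.107 and the median 0.29, 0.05 and 0.08, while without knockout cocultured 3 the median was 0.80.

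The other process lists were not called in knockout cells in the main fit. Of 25 cholesterol genes, Cyp51 (1.97) and Hsd17b7 (1.84) rose (2 passing when adjusted over the list alone, median 0.77, camera adjusted p = 0.0608, called in 9 alternative settings), and of 23 interferon genes, Stat2 (-1.16) and Usp18 (-2.39) fell (median -0.06, camera adjusted p = 0.778). Of 29 lysosome and exocytosis genes, Stx11 (3.58), the cathepsin Ctsb (1.60) and Rab27b (1.25) rose and 2 fell, Rab3a (-2.92) among them (median 0.08, of either sign by scaling, camera adjusted p = 0.650). Of 23 immediate early genes, Atf3 (5.75), Klf4 (4.83) and Nfkbia (3.64) rose and Egr1 (-2.21) fell (median 0.61, camera adjusted p = 0.652). Of 30 cell cycle genes 0 passed, with Cdt1 at 1.15 and Ccnb1 at 1.05 (median 0.30, camera adjusted p = 0.381). That list was called in 3 alternative settings, at 0.75 (camera adjusted p = 0.00615) without knockout cocultured 3. Calls of Asns, Hsd17b7, Stat2, Ctsb, Rab27b, Atf3 and Egr1 ended without at least 1 array, at adjusted p up to 0.127 for Egr1 without knockout cocultured 1, and those of Asns, Hsd17b7, Stat2, Ctsb and Rab27b with at least 1 other scaling, at up to 0.246 for Rab27b with the authors' normalized values.

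Fibroblast markers stood higher in knockout cocultured cells as well. Of 33 measured, 16 rose, 1 fell and 16 did not pass, with 21 passing when adjusted over the list alone. Serpinh1, Col3a1, Dcn, Col1a1 and Igfbp7 were at least 134-fold, 62.9-fold, 55.9-fold, 45.2-fold and 20.1-fold higher, while Timp3 was at least 61.8-fold lower. The median was 2.88 (camera adjusted p = 5.39e-08), 1.49 with bounds, and 2.37, 3.07 and 5.41 within slides 1, 2 and 4 (0.97, 1.0 and 3.60 with readings below background at the lowest signal well above it), a call lost at adjusted p = 0.851 with an estimated correlation. With normexp background correction the calls of Col1a1 and Col3a1 ended (adjusted p = 0.100 and 0.0819), and those of Col1a1, Igfbp7 and Mgarp with the authors' normalized values (adjusted p = 0.0660, 0.136 and 0.204). Of 13 macrophage markers Cd68 (2.95) and Cd14 (2.51) rose, and of 3 basophil markers Mcpt8 rose. Of 6 MHC class II markers H2-Ab1 (-1.47) fell and of 8 megakaryocyte markers Gp1ba (-1.28, SE 0.30) fell. None of the 5 erythroid, 4 neutrophil, 2 eosinophil and 3 lymphocyte markers passed. The largest other changes without overlap were the rises of Ptx3, Nid1, Steap1 and Cxcl5, at least 62.6-fold, 54.3-fold, 58.1-fold and 47.2-fold, and the falls of Trgv4, Cyp4a12b and Mgarp, at least 72.3-fold, 58.7-fold and 28.3-fold. Igh (-6.85), Pigz (-6.66), Ighv1-54 (-6.55), Ighv1-12 (-6.33), Cyp4a12a (-5.73) and the plakophilin Pkp1 (-5.66) fell too. Of the 22 genes in the authors' table, 11 rose and 0 fell, with 16 passing when adjusted over the list alone, again no independent evidence. Calls of Cd14, Cd68, H2-Ab1 and the chemokine Cx3cl1 (4.09) ended without at least 1 array, at adjusted p up to 0.141 for H2-Ab1 without knockout cocultured 1. With the authors' normalized values the calls of Cd14, H2-Ab1 and Cx3cl1 ended, at adjusted p of 1, 0.0724 and 0.498, Cd14 standing at 0. The phospholipase A2 list had a mean above 0 beside a median below 0, and the MHC class II list the reverse.

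**Figure D3:**
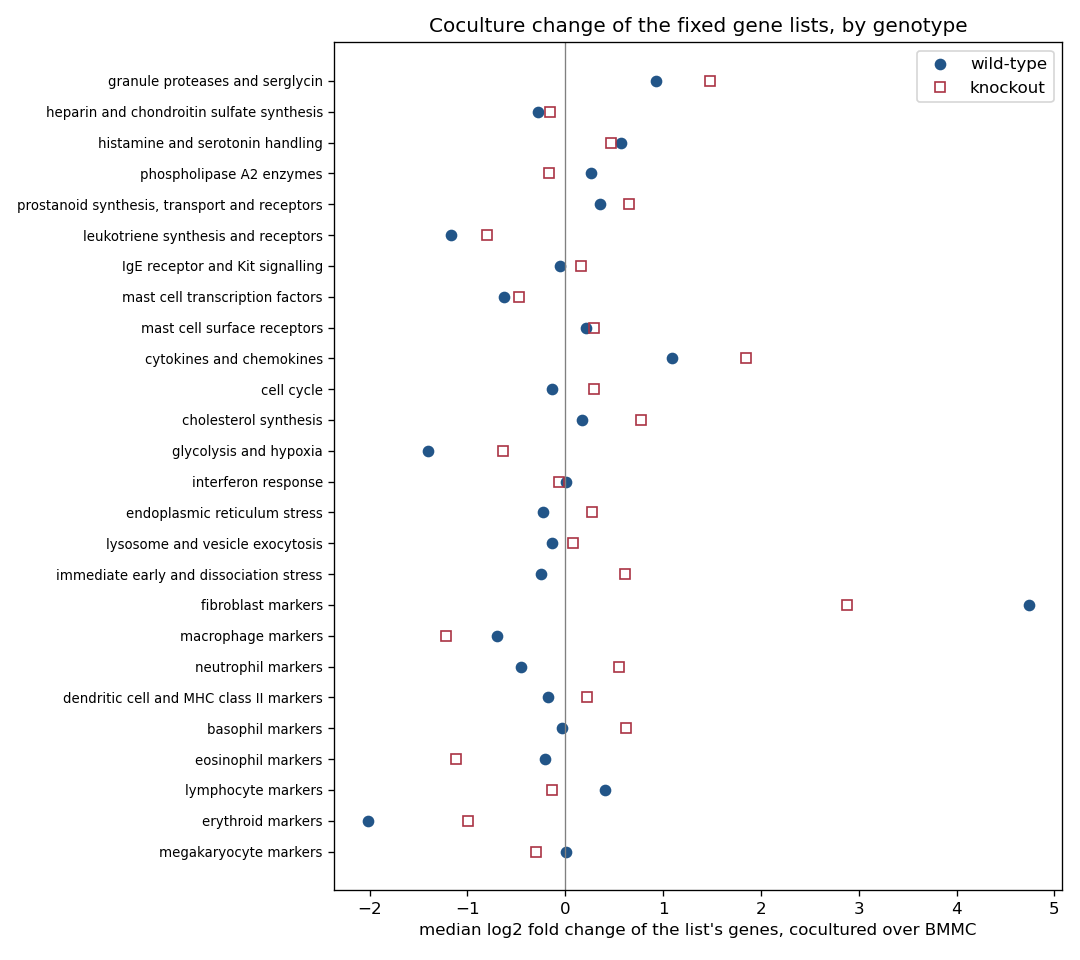
Each row gives, for 1 gene list, the median log2 change of its measured genes after coculture, with a filled circle for wild-type and an open square for knockout cells and a line at 0. Fibroblast markers lie farthest to the right, at 4.74 in wild-type and 2.88 in knockout cells.

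Knockout and wild-type BMMCs were compared to see what Pla2g3 loss did before maturation. The Pla2g3 probe was at -1.57 ± 0.28 (SD, n = 4) in arrays labelled knockout and -3.80 ± 0.87 (SD, n = 3) in arrays labelled wild-type, 2.22 higher (SE 0.54) in knockout, with no overlap, opposite to what loss of the transcript would give. It did not pass over all genes (adjusted p = 1) and passed when adjusted over the phospholipase A2 list alone, and the difference within slides 1, 2 and 3 was 2.31, at least 2.88 and 1.36. The deleted part of the gene is not given in the sources used here, and a probe outside it would not show the deletion. That alone would not make the level higher in knockout arrays, and the cause was not tested. The direction of each knockout comparison rests on the labels as given. Tlr2, a receptor for bacterial lipoproteins, was at 1.02 ± 0.24 (SD, n = 4) in knockout and -3.98 ± 2.15 (SD, n = 3) in wild-type BMMCs (log2 difference 5.0, SE 1.15, adjusted p = 1) and passed only when adjusted over the surface receptor list alone. Hdc (-1.13, SE 0.50), Tpsb2 (-0.94, SE 0.38), Cpa3 (-0.43), Cma1 (-0.40), Fcer1a (-0.31), Ms4a2 (-0.19), Ndst2 (-0.23), Mcpt4 (-0.23), Ptgs1 (-0.64), Hpgds (0.21) and Kit (0.01) did not pass, each at adjusted p = 1, and Ptgs2 was below background in both groups.

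For genes changed by knockout before coculture, limma called 0 of 16009, with a lowest adjusted p of 0.0760 and 170 genes at an unadjusted p under 0.05 where chance would give 800. In 635 genes (3.97%) the groups did not overlap, against 5.71% by chance. The count was 1 with quantile normalization, 2 with array weights and 2 without knockout BMMC 3, and 0 with the other settings tried. Changes of 2 on the log2 scale put into simulated data with independent noise were recovered in 53.7% of cases at this group size, a share that need not hold for the arrays.

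Among the lists, the 3 measured basophil markers had a median of -0.89 (camera adjusted p = 0.00628), with Prss34 at -2.01 (SE 0.87) and Mcpt8 at -0.89 (SE 0.48), and 0 members passing over all genes or when adjusted over the list alone. The median within slides 1, 2 and 3 was -0.18, -0.79 and -1.77 and turned to 0.14 with the authors' normalized values, and the call was lost at adjusted p = 0.747 with an estimated correlation, 0.806 with the authors' normalized values, 0.185 with normexp background correction, 0.177 without wild-type BMMC 2 (median -0.67) and 0.169 without knockout BMMC 3 (median -0.43). On that last array Prss34 (-3.73) and Mcpt8 (-4.90) were below background. No other list was called in the main fit, at the preset correlation. With the filter on all arrays the granule proteases were called (median -0.39, adjusted p = 0.00133), and with no filter on dim probes the neutrophil markers (-0.29, adjusted p = 0.013), also called with median scaling (-0.71, adjusted p = 0.0304). Leaving out single arrays called these 2 lists and others, interferon response most clearly without wild-type BMMC 2 (0.63, adjusted p = 2.08e-11). The phospholipase A2 list was called in 11 alternative settings and the cell cycle list in 8. With a replicate block, which pairs arrays of the same number, the cell cycle list (median 0.10, camera adjusted p = 0.0085) and the phospholipase A2 list (0.08, camera adjusted p = 0.0394), which holds Pla2g3 itself, were called. With slide as a fixed block they stood at 0.15 (adjusted p = 0.00149) and -0.01 (0.0363). The estimated correlation was not run with a block and gave adjusted p = 0.966 and 0.747 without one. Without a block 0 members of any list passed over all genes. The granule proteases had a median of -0.38, of either sign by scaling (camera adjusted p = 0.119), with Tpsg1 at -2.84 (SE 0.86) and Tpsab1 at least 2.08-fold higher. The heparin and chondroitin list -0.10, likewise of either sign (adjusted p = 0.859), with Csgalnact1 at least 3.74-fold higher. The histamine and serotonin list stood at 0.04, with the decarboxylase Ddc at 1.66 (SE 0.83), and the fibroblast list at -0.05, of either sign by scaling. The neutrophil list was at -0.77, with S100a9 at -2.79 (SE 1.48), and at -0.27, -2.69 and -0.01 within slides 1, 2 and 3, so its value rested mainly on slide 2. The test pointed up beside a median below 0 for the heparin, surface receptor, cholesterol, interferon and fibroblast lists, and the macrophage list had a mean below 0 beside a median above 0. Of the 22 genes that the authors listed 0 passed, and 17 lay below 0, which is no independent evidence, since the list was drawn from these arrays.

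Knockout and wild-type cocultured cells were compared to see what Pla2g3 loss did to matured cells. Y-linked signal was present on 4 of 4 wild-type and 1 of 3 knockout cocultured arrays, so donor sex was uneven between these groups. The Pla2g3 probe was at -2.32 ± 0.78 (SD, n = 3) in arrays labelled knockout and -3.48 ± 0.96 (SD, n = 4) in arrays labelled wild-type (log2 difference 1.17, SE 0.54, adjusted p = 0.796), and the difference was at least 2.39 and 2.08 within slides 2 and 4. Hdc was at 5.39 ± 0.67 (SD, n = 3) and 6.02 ± 0.45 (SD, n = 4), a difference of -0.63 (SE 0.50, adjusted p = 0.796), and -0.94 and -1.05 within slides 2 and 4. Mcpt4 was at 4.58 ± 1.65 (SD, n = 3) and 5.93 ± 2.98 (SD, n = 4), a difference of -1.35 (SE 1.33, adjusted p = 0.814), and -3.61 and 4.73 within slides 2 and 4. Mcpt1 differed by -3.12 (SE 2.37, adjusted p = 0.796), by -8.15 within slide 2, and by at least 7.46 within slide 4. Hpgds (0.45), Fcer1a (0.50), Ptgs2 (0.48), Kit (0.28), Cma1 (0.22), Cpa3 (0.20), Ms4a2 (0.14), Tpsb2 (0.10), Ptgs1 (-0.08) and Ndst2 (-0.29) did not pass, at adjusted p of 0.796 to 0.978.

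For genes changed by knockout after coculture, limma called 0 of 16009, with a lowest adjusted p of 0.796 and 608 genes at an unadjusted p under 0.05 where chance would give 800. In 289 genes (1.81%) the groups did not overlap, against 5.71% by chance. The count was 0 whichever array was left out alone and 1 with the authors' normalized values. It was 6919 with array weights, which gave wild-type cocultured 3 and knockout cocultured 3 the lowest weights, 0.177 and 0.150. It was 4049 without that pair and 4231 without slide 4. The last counts rest on leaving out or weighing down arrays because of where they stood, so they are no test of genotype.

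Fibroblast markers differed among the cocultured arrays as the second principal component did. Their median level was 0.20, 2.31, -2.46 and 0.64 on wild-type cocultured 1 to 4 and -3.09, -1.54 and -0.31 on knockout cocultured 1 to 3, against -6.41 to -4.80, below background, on BMMC arrays. The list's median difference was -1.78 (camera adjusted p = 2.68e-11, lost at adjusted p = 0.747 with an estimated correlation), with Col3a1 at -2.47 (SE 1.08) and Lum at least 1.38-fold lower, and -2.29 and 1.98 within slides 2 and 4. The endoplasmic reticulum stress list was at 0.52 (camera adjusted p = 0.000713, lost at adjusted p = 0.966 with an estimated correlation), with Asns at 1.22 and Dnajb9 at 1.03, and 0.94 and -1.41 within slides 2 and 4. The cholesterol list was at 0.55 (camera adjusted p = 0.00144, lost at adjusted p = 0.966 with an estimated correlation), with Sc5d at 0.98 and Stard4 at 0.85, and 0.56 and -1.23 within those slides. The cell cycle list was at 0.41 (camera adjusted p = 0.00561, lost at adjusted p = 0.966 with an estimated correlation), with Ccne2 at 0.99 and Mcm5 at 0.83, and 0.88 and -0.67 within those slides. No member of these 4 lists passed over all genes or when adjusted over the list alone, and within slides the direction turned in each. Leaving out knockout cocultured 1 ended the call of the endoplasmic reticulum stress list (median 0.28, adjusted p = 0.0840) and of the cholesterol list (0.27, adjusted p = 0.236), leaving out wild-type cocultured 4 that of the cholesterol list (0.29, adjusted p = 0.0852), and leaving out knockout cocultured 2 that of the cell cycle list (0.06, adjusted p = 0.973). The authors' normalized values ended those of the endoplasmic reticulum stress list (adjusted p = 0.0631) and the cell cycle list (0.106), and slide as a fixed block those of the cholesterol list (0.28, adjusted p = 0.138) and the cell cycle list (0.08, adjusted p = 0.981). Other omissions kept the calls and moved the median. Without knockout cocultured 3 the endoplasmic reticulum stress, cholesterol and cell cycle lists stood at 0.85, 0.99 and 0.82. The first of them was at 0.86, 0.35 and 0.32 without wild-type cocultured 3, wild-type cocultured 4 and knockout cocultured 2, and the fibroblast list at -1.08 without wild-type cocultured 2.

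No other list was called after coculture in the main fit. With slide as a fixed block the glycolysis list (0.38, adjusted p = 0.00496) and the interferon list (-0.49, adjusted p = 0.0119) were called, and the lymphocyte list was called in 9 alternative settings, with a replicate block (-0.66, adjusted p = 0.016) among them. Granule proteases had a median of 0.10 (camera adjusted p = 0.918), the cytokines -0.03 with Il13 at -1.13 (1.99 and -1.77 within slides 2 and 4), the histamine list -0.16 with Ddc at 2.44 (SE 0.83), and the leukotriene list 0.01 with Abcc1 at 0.70 (SE 0.28), all of either sign by scaling. Of the 26 lists, 22 had opposite signs within slides 2 and 4, where each cocultured group had 1 array. In 4 of the 22 both differences exceeded 1 in size. The macrophage list was at -0.58 with the complement gene C1qc at -3.21 (SE 1.12), and each gene named here had an adjusted p = 0.796. Mean and median, or the test and the median, differed in sign for the granule protease, histamine, prostanoid, leukotriene and MHC class II lists. Of the 22 genes that the authors listed 0 passed, and 17 lay below 0, Cxcl12 at -2.83 (SE 1.41) among them. Since the list was drawn from these arrays, this is no independent evidence.

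The difference between the genotypes in their coculture change was tested as an interaction, the question of whether Pla2g3 loss altered maturation. Donor sex, uneven between the cocultured genotypes, enters this difference too. The Pla2g3 probe changed by 0.31 in wild-type and -0.74 in knockout cells, a difference of -1.05 (SE 0.76, adjusted p = 0.994). Hdc (0.50, SE 0.70), Tpsb2 (1.04, SE 0.54), Mcpt4 (-1.12, SE 1.88), Tlr2 (-4.36, SE 1.62) and the cathepsin Ctsc (1.17, SE 0.44) did not pass, each at adjusted p = 0.994. Mcpt1 and Csgalnact1 did not pass either, and no difference is given for them because both were below background on all wild-type BMMC arrays. Thus Tpsb2, which passed in knockout and not in wild-type cells, was not shown to differ between them. Of genes whose coculture change differs between genotypes limma called 0, with 131 at an unadjusted p under 0.05 where chance would give 800. The count was 0 whichever array was left out alone, 3487 with array weights, 2037 without the cocultured pair of slide 4 and 1760 without slide 4. Changes of 2 on the log2 scale were recovered here in 26.9% of cases simulated with independent noise, which need not hold for the arrays.

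The fibroblast list differed by -1.75 (camera adjusted p = 2.68e-11, lost at adjusted p = 0.747 with an estimated correlation), a median of fitted values whose BMMC part lay below background. It was -1.05, -2.68 and -1.16 without wild-type cocultured 2, wild-type cocultured 3 and knockout cocultured 1. The endoplasmic reticulum stress list differed by 0.60 (adjusted p = 0.000945, lost at adjusted p = 0.966 with an estimated correlation; -0.29 and adjusted p = 0.245 with the authors' normalized values), with Asns at 1.47, and the cholesterol list by 0.65 (adjusted p = 0.0146, lost at adjusted p = 0.966 with an estimated correlation), with Sc5d at 1.21. With slide as a fixed block the glycolysis list (0.61, adjusted p = 0.00426) and the interferon list (-0.60, adjusted p = 0.00535), uncalled in the main fit, were called. The glycolysis list was called in 9 alternative settings. Omissions of 1 array added other calls. Among them were interferon response (-1.15, adjusted p = 3.18e-09) and macrophage markers (-0.94, adjusted p = 5.76e-07) without wild-type BMMC 2, and the cell cycle (0.82, adjusted p = 0.00209) without knockout cocultured 3. No member of any list passed in the main fit, and the cholesterol call ended with quantile normalization (adjusted p = 0.0538), with slide as a fixed block (0.452) and without any of 5 arrays, at adjusted p from 0.0684 without wild-type cocultured 2 to 0.387 without knockout cocultured 1. The cholesterol median was 0.34, 0.38 and 1.1 without knockout cocultured 1, wild-type cocultured 4 and knockout cocultured 3, and that of the endoplasmic reticulum stress list 0.98 and 0.94 without wild-type cocultured 3 and knockout cocultured 3.

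The size of the coculture response was compared over 4917 genes called in all cocultured against all BMMC arrays without regard to genotype, 2434 higher and 2483 lower. Their mean change in the pooled direction was 1.60 in wild-type and 1.52 in knockout cells, a ratio of 0.951 and a difference of -0.079 log2. The difference was within what exchanging genotype labels gave (exact two-sided permutation p = 0.507 over 1225 splits, which can give no p below 0.00082). Genes whose response differs between the genotypes add to the spread of that pooled fit and are chosen less readily, which draws the ratio towards 1. The value also covers all RNA of the harvest, where fibroblast markers rose by medians of 4.74 in wild-type and 2.88 in knockout cells, and not mast cells alone.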

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

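The tests in this part were chosen after the patterns had been seen, though the limits of the donor sex test were written before its count was computed.

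Mcpt1, a mucosal mast cell chymase, was at -6.36, below background, on wild-type cocultured 3, far from the other wild-type cocultured arrays. The fibroblast list was at -4.80 on knockout BMMC 3 and the prostanoid list at 0.26 on knockout BMMC 4, each far from the other knockout BMMC arrays. On knockout BMMC 3 the lowest signal called well above background was -2.75, against -4.53 to -4.20 on the other 3, so the fibroblast level there lies below background. The immediate early list was at 1.69 on wild-type cocultured 1. Of 122 groups tested, 4 held an array this far from the others, where chance gives 5%. The coculture change differed between the genotypes for 3 lists by camera on the interaction, cholesterol synthesis at 0.65, endoplasmic reticulum stress at 0.60 and fibroblast markers at -1.75, and 0 of these calls held with an estimated correlation. Xist, which is transcribed from the inactive X chromosome of female cells, was not below -0.84 on any cocultured array with Y-linked signal, although the comparisons of the report do not use it.

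Fibroblast markers and the mast cell proteases Mcpt1, Mcpt2, Mcpt4 and Cma2 split the cocultured arrays across the genotype labels, with wild-type cocultured 3 beside knockout cocultured 1 and 2, and knockout cocultured 3 beside the other wild-type arrays. The granule protease list as a whole did not, with knockout differences of 0.02 and -0.02 within slides 2 and 4. A slide effect is argued against, since fibroblast markers differed by -2.29 on slide 2 and 1.98 on slide 4. Fibroblast RNA in the harvest may account for the fibroblast part, since Xist in Y-positive cocultured arrays exceeded that in Y-positive BMMC arrays by at least 3.35, although the sex of the fibroblasts is not given and the labels report over 99% pure cells. It is argued against for the 4 proteases, since RNA of cells that lack mast cell genes would leave their level relative to Cpa3, Cma1, Kit and Fcer1a as it was. That level differed by -4.86 within slide 2 and by at least 5.11 within slide 4, where Mcpt1 of wild-type cocultured 3 was set to the lowest signal well above background. It was higher by at least 4.86 each time on the array with more fibroblast signal. Variation in maturation stays open and was not tested. Exchanged labels of the slide 4 pair cannot be told apart from correct ones. On 7 genes separating the BMMC genotypes wild-type cocultured 3 scored 0.73 (SE 0.74) and knockout cocultured 3 -0.06 (SE 0.38), a difference of 0.79, on the sides of their labels by sign. The same score put wild-type cocultured 4, which is not in question, on the knockout side (-0.43, SE 0.25), and the requirement that a score exceed its SE was added after these scores were seen. On broader sets of 606 genes and of 49 genes on chromosome 11 every other cocultured array scored opposite to its label, so these sets decide nothing. The Pla2g3 probe ran the way of the labels, at -4.14 on wild-type cocultured 3 and -1.97 on knockout cocultured 3, but it is 1 probe near background and wild-type cocultured 4 stood at -2.22.

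Pla2g3 and its neighbours on chromosome 11 separated the BMMC genotypes more often than other genes did. Within 10 Mb of the probe 12 of 94 genes separated them (12.8%), Morc2a, Mtfp1, Nipsnap1 and Ddc among them. Of 15623 genes 3.85% did, and 0.0143 of random runs of neighbours held as many as the region. Any gap above 0 counted. Morc2a was at 1.57 to 1.60 in wild-type and 1.33 to 1.56 in knockout BMMCs, while the gap of Abca13 was 1.25. On chromosome 4, from 150423080 to 155402849, 21 of 74 genes did, and 0.001 of shuffles gave as full a window, the smallest share 1000 shuffles can give. Broad small shifts of gene-dense regions are argued against for chromosome 4. There 5 of 27 genes separated by at least 0.5, Prdm16 and Tnfrsf14 among them, lay in 1 window, again at 0.001. The windows left out chromosome 11, so small shifts around Pla2g3 were not tested. Segments of another strain kept beside the targeted gene and elsewhere are a candidate explanation for the BMMC arrays, where effects of Pla2g3 loss itself stay open. A segment would be present in cocultured cells too. There 49 genes of chromosome 11 that separated the BMMC genotypes scored 1.175, 1.191 and -2.119 on knockout cocultured 1 to 3. On wild-type cocultured 1 to 4 they scored -1.004, -1.001, 1.158 and -0.753, above 0 being the wild-type side. That set was drawn from all of chromosome 11, and 12 of its 49 genes lay within 10 Mb of the Pla2g3 probe. None of it covers the chromosome 4 window. Its scores therefore cannot decide whether a segment is present.

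Genes called for coculture could also reflect uneven donor sex. Y-linked signal was present on 1 of 3 wild-type BMMC, 1 of 4 knockout BMMC, 4 of 4 wild-type cocultured and 1 of 3 knockout cocultured arrays. With a term for it the count of genes changed by coculture in wild-type cells was 1084, against 2064 without it, and 1025 of the 1084 were shared. Sex and coculture overlap too far in wild-type cells for this to decide, and in knockout cells the count was 2122 against 2285. Y-linked signal was also uneven between the cocultured genotypes, so donor sex enters knockout after coculture and the interaction as well. No biological effect of sex was tested.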

How the results depend on the processing

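The donor sex term, the omission of slide 4 or its cocultured pair and the authors' raw values were chosen after seeing the data. Named genes were not tested again under these 4 settings. Under the others, named gene calls kept their direction in 3342 refits with the call and in 453 without it, Cd14 in knockout coculture standing at 0 with the authors' normalized values, and 465 differences within a slide or on another probe, which have no test, had the same sign. Stat5b in wild-type coculture, which the naming rule did not cover, stood at 0.31 on 1 of 2 other probes. Lists stayed called in the same direction in 415 refits and uncalled in 3019, gained a call in 112 and lost one in 58, and 11 reversed, 5 of them within slide 4 and without a test. For genes changed by coculture in wild-type cells the count was 1031 with the authors' normalized values (8994 genes tested), 1251 with the filter on all arrays (11104 tested), 4921 with array weights, 1084 with the donor sex term, 3900 without slide 4, 3785 without its cocultured pair and 1119 to 2684 leaving out each array. For genes changed by coculture in knockout cells it was 1412 with median scaling, 933 with the authors' normalized values, 1357 with no filter (27948 tested), 6973 with array weights, 4652 without slide 4, 4946 without its cocultured pair and 1069 to 3144 leaving out each array. With a replicate block it was 1231, although between the groups of this comparison, of coculture in wild-type cells and of knockout after coculture arrays of the same number did not deviate together (r of -0.544 to 0.12 over 9 pairs). For knockout before coculture, where they did, the block changed no call other than those of the cell cycle and phospholipase A2 lists. For genes changed by knockout before coculture it was 1 with quantile normalization, 2 with array weights and 0 to 2 leaving out each array. For genes changed by knockout after coculture it was 1 with the authors' normalized values, 6919 with array weights, 4231 without slide 4 and 4049 without its cocultured pair. For genes whose coculture change differs between genotypes it was 3487, 1760 and 2037 under the last 3 settings. Of the fixed gene lists 17 were called, 8 with the filter on all arrays, 0 with an estimated correlation and 14 to 26 leaving out each array. Slide as a fixed block ended the calls of 17 named genes, each of which also ended without at least 1 array. These were Grp, Chac1, Klf1, Dusp2, Gbp2, Ltc4s, Cd68, Tlr4 and Mcpt1 in wild-type coculture and H2-Ab1, Ugdh, Chst12, Cysltr2, Cd68, Plaat3, Pnpla8 and Pla2g15 in knockout coculture. Of lists it ended 4 and gained 7, the transcription factors in knockout coculture among them. Slide as a random block ended 1, the cell cycle list after coculture, and gained 5, the prostanoid list in both cocultures among them (adjusted p = 0.0372 and 0.0311). The replicate block ended the calls of 32 named genes and 2 lists and gained 7 list calls. Of the 32, all but Ltb4r1 in knockout coculture also ended without at least 1 array. List calls gained by setting were 10 without wild-type BMMC 2, 6 with no filter on dim probes and 6 with median scaling. No filter on dim probes ended the calls of 25 named genes, all of which also ended without at least 1 array. The donor sex term ended the endoplasmic reticulum stress call after coculture and the cholesterol call of the interaction. The filter on all arrays ended 11 list calls, the granule protease list in wild-type and the cytokine list in both cocultures among them, and the call of Ptx3 in knockout coculture. With that filter, which left few fibroblast members, fibroblast markers, coculture_in_wild_type reversed to -0.24, fibroblast markers, coculture_in_knockout to -0.21 and fibroblast markers, knockout_after to 0.38. Within slide 4, endoplasmic reticulum stress, coculture_in_knockout was -0.40, and after coculture the knockout differences of cell cycle, knockout_after (-0.67), cholesterol synthesis, knockout_after (-1.23), endoplasmic reticulum stress, knockout_after (-1.41) and fibroblast markers, knockout_after (1.98) reversed. The interferon response, knockout_before was 0.17 with the authors' normalized values and ranged from -0.43 to 0.63 leaving out each array, and interferon response, knockout_after was 0.63 with the donor sex term. Apart from fewer genes tested or arrays used, the cause was not tested. Probes near background limit what the arrays show, since only 43.0% to 55.9% were well above it.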

Other observations

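The split tests in this part were chosen before any result was seen, and the comparison of array pairs after. For coculture in wild-type cells 1 of 35 splits of the arrays, the real one, gave 2064 genes, and the highest other gave 1319. That other split put wild-type cocultured 3 with the wild-type BMMC arrays. A share of 1 in 35 is the smallest this test can give, so it makes chance unlikely without excluding it. It does not separate coculture from donor sex, and with the term for Y-linked signal the count was 1084. For coculture in knockout cells 1 of 35 splits gave 2285 genes and the highest other gave 3, again the smallest share that 35 splits can give. For knockout before and after coculture and for the interaction the real count was 0. All 35, 35 and 100 splits reach that count by necessity, so the comparison tests nothing there. The highest other counts were 5, 5428 and 3320. For knockout after coculture the split of wild-type cocultured 3 with knockout cocultured 1 and 2 against the rest gave the 5428 genes, which points to a structure of the samples other than the labelled genotype.

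After group means were removed, pairs of arrays on the same slide had a median r of 0.18 over 17 pairs, against -0.07 over 56 pairs on different slides. These are correlations across genes, which are not independent replicates.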
